A study of Mus musculus with 6 samples.

How the data were processed

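The study compared testes of Arid4bSCKO and control mice at postnatal day 1.5, with 3 pools of 4 testes in each of 2 groups. Per the labels' protocols, total RNA was purified and treated with DNase, and strand-preserving poly(A) libraries (TruSeq Stranded mRNA, with dUTP in the second strand) were read from both ends for 50 bases. The mice were hybrids of C57BL6/J and 129/SvEv. The submitters' processing notes list STAR 2.4 and the mm10 genome. The counting tool, its use of strand, the annotation release and the normalization are not given in the sources used here.

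The measurements came from 1 table of the authors' comparison with 22320 genes. Per the file headers and column descriptions, it holds for each gene the authors' mean over the 3 libraries of a group of log2(normalized count + 1), a log2 fold change as the ratio of the group medians, an unadjusted p-value from an equal-variance comparison of the groups, and an FDR. Values per library were not analysed here. The deposited FDR was recomputed from the deposited p-values by the Benjamini-Hochberg method over all 22320 genes and agreed to a relative difference of 4.78e-05. Genes read in a single library were taken to be those with a p-value of 0.374 and a mean of 0 in the other group. This is the p-value that 4 residual degrees of freedom give for such a gene. In 529 rows the control mean was 0 and the Arid4bSCKO mean matched a value of 0.1 log2 in 1 library, which was read as a filled-in value. These rows were left out of the tests added here, but the deposited FDR, adjusted over all 22320 genes, includes them.

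Depth was read from the low values. Of 1130 genes with reads in only 1 library, 91.2% had a mean that equalled a whole multiple of a fixed step within 0.001. The steps were the most common values per group among these same genes. Genes at exactly 1 step therefore counted by construction, and the share is not an independent check. The step, the worth of 1 read, was 1.28, 1.30 and 1.45 normalized counts in the Arid4bSCKO libraries and 1.20, 1.23 and 1.25 in the control libraries. These steps and the summed group means put the depth at about 17.5 M and 18.6 M reads per library. Scaling therefore gave a read 9.56% more weight in Arid4bSCKO, and genes with few reads carry counting noise that the log2 scale compresses.

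The difference between the groups is the Arid4bSCKO mean less the control mean. Its standard error was worked back from the deposited p-value with 4 degrees of freedom, and 95% intervals follow from it. Folds are on the log2(normalized count + 1) scale, which understates changes of genes with few reads. As fixed before the data were examined for a table of group means, the main result is the authors' FDR below 0.05. For such a table the plan allowed no test of single genes beyond the authors' own, and the moderated test departs from it. A moderated test was added after the table had been examined, because a variance estimated from 3 and 3 libraries made the deposited test sensitive to genes with a very small spread. The implied variance of each of 19095 genes with a mean level of at least 1 was shrunk with limma 3.58.1 (squeezeVar with a trend on level and robust fitting, median prior degrees of freedom 7.46) in R 4.3.3, and the p-values were adjusted by the Benjamini-Hochberg method over those genes. The labels do not say that pools came from separate litters, so the p-values measure the spread between these pools. How many pools show a direction was not analysed here.

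The moderated test was tested on simulated data, with 200 of 19092 genes changed. It recovered 97.0% of 100 genes with a 1 log2 change and 100% of 100 with a 2 log2 change, where a test of the deposited kind recovered 30.0% and 86.0%. False calls made up 3.43% and 13.4% of all calls. The simulated genes were independent of each other, their dispersions came from a narrow range, and the changed genes lay above a minimum level. These rates hold for that setting and do not measure the false calls in the data.

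Gene lists, 24 in number, were written before the data were examined: Sertoli cell, stem cell niche, germ cell, Leydig cell, myoid, stroma, endothelium, macrophage, erythroid, mesonephric and epididymal, granulosa, basement membrane, junctions, polarity, proliferation, arrest and p53, Sin3 and retinoblastoma family, imprinted, Rhox, retinoic acid, cholesterol, immediate-early and stress, mitochondrial and sex-linked genes. Some lists share members, and a shared gene counts in each of its lists. The 13 symbols written for the mitochondrial list matched no symbol of the table, and the 10 mitochondrial chromosome genes it holds under other symbols are described in their place. For each list, members passing each test were counted, p-values were also adjusted over the list alone, and the median was placed among 10000 random lists drawn from 20 bins of expression. A set test on the moderated statistic (cameraPR in limma, preset correlation 0.01, adjusted over the lists) was added after the data had been seen. An inter-gene correlation could not be estimated from group means, and a preset correlation of 0.05 was run as well, under which the Sin3 list alone lost its call. Both presets are assumptions, and neither is a bound. Members of a list that vary together more strongly would have larger p-values.

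The genes named were set by a rule: Arid4b and Arid4a, then the 10 largest rises and falls among genes past the FDR with a level of at least 4.32, a bound set by rank over the whole table, and an established name, or all if fewer, then up to 4 passing members of each list, or the 2 with the smallest p if none passed. Other genes named were chosen after their values were seen. These are Amh, Sox9, Wt1, Dhh, Dmrt1, Cldn11, Krt18, Gdnf, Kitl, Lif, Ccl9, Cyp26b1, Ddx4, Gfra1, Pf4, Ptch1, Cdkn1a, Junb, Hspa1b, Itga6, Lama3, Gja1, Rbl1, Rhox5, Foxl2, H2-M2, Nkx1-2, Edf1, Cd14, Fcer1g, Lyz2, Tyrobp, Emr1, Bax, Fas and the genes of the closing observations. Mdm2, Ccng1, Zmat3, Pmaip1, Inhbb and Xist were also chosen after their values were seen. Transcript lengths and positions came from GENCODE M21 on GRCm38, the assembly that mm10 names. Symbols or gene identifiers were matched for 91.8% of the genes at a level of 1 or more, and 99.8% of 9617 positions compared overlapped those of the table. Processing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives varied the threshold, the fold minimum, the filter on low levels, the shrinkage, the centring, a correction for transcript length and the kind of mean. The setting without the trend on level also left out robust fitting, so its effect cannot be credited to either alone.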

Results

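Messenger RNA was sequenced from whole testes of mice at postnatal day 1.5, when Sertoli cells, the somatic cells of the testis cords, surround the germ cells from which spermatogonial stem cells form. The Arid4bSCKO mice carried 1 floxed and 1 null allele of Arid4b with Cre recombinase driven by the Amh promoter, which is active in Sertoli cells. Control mice carried the same floxed allele and Cre with a wild-type allele in place of the null one, so the genotypes also differed outside Sertoli cells. ARID4B binds the retinoblastoma protein and is a partner of the Sin3 histone deacetylase corepressor. Each group had 3 pools of 4 testes. The values are the authors' means per group and their comparison of 22320 genes, without a value per pool. The worth of 1 read, taken from genes read in a single library, placed the depth at about 17.5 M reads per Arid4bSCKO library and 18.6 M per control library (M, mega). The spread between pools that the deposited p implies had a median SD of 0.81 log2 units for genes at levels from 1 to 3 and 0.12 for genes at levels from 9 to 11.

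The targeted gene was lower in the Arid4bSCKO testes. Arid4b (chromosome 13, 14063232 to 14199603, plus strand, mm10) stood at 35.1% of control, a log2 difference of -1.51 with a 95% interval of -1.82 to -1.21. In the authors' deposited table its mean log2 levels were 8.68 and 10.19 and its FDR was 0.0535, just outside the threshold of 0.05. It passed a moderated limma test on the same means, chosen after the table had been examined, at an adjusted p of 2.23e-05. The paralog Arid4a (chromosome 12) differed by -0.15 (95% interval -0.46 to 0.17), within the spread between pools. Levels of Arid4b in single pools were not analysed here.

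The main question was which genes differed between Arid4bSCKO and control testes. Whole testes were read, so a difference cannot be assigned to Sertoli cells from these values. Hrk, a BH3-only activator of apoptosis, rose most among the genes named by rule, by 6.59 log2 units (95% interval 5.54 to 7.65), or 96.6-fold on the log2(normalized count + 1) scale. Wnt11, a secreted Wnt ligand, rose by 2.76 (2.30 to 3.22), Klhl30 by 2.66 (2.20 to 3.12), and Insc, an adaptor of spindle orientation, by 2.63 (2.41 to 2.85). Smaller rises were seen for Gp49a, the LIM protein gene Pdlim1 (1.33, 95% interval 1.13 to 1.53), the small GTPase gene Rhob (1.29), Tesc (1.22), Shc4 (1.17) and the defensin gene Defb36 (1.10). Hrk and Tesc lie close together on chromosome 5, at 118164648 to 118189478 and 118027743 to 118061878. Among the genes that fell, Slc25a42, a mitochondrial coenzyme A carrier, fell by 1.54 (95% interval -1.80 to -1.28), Pipox, a peroxisomal oxidase gene, fell by 1.47 (-1.74 to -1.20) and Cxxc4, a zinc finger gene, fell by 1.04 (-1.23 to -0.85). Dkc1, Suv420h1, Zfp740 and Chsy1 fell by 0.32, 0.31, 0.30 and 0.29. Removing the trend over transcript length left Suv420h1, Zfp740 and Chsy1 outside the moderated test, with adjusted p-values of 0.128, 0.0514 and 0.0558. Without the trend of the spread on level and robust fitting, none of the 4 small falls passed it. Their adjusted p-values then ran from 0.0828 for Dkc1 to 0.0955 for Chsy1.

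These genes come from 58 that passed an FDR of 0.05 in the authors' deposited table, 31 higher and 27 lower in Arid4bSCKO. Of the 58, 21 had exactly 1 read in each library of one group and none in the other, 16 of them read only in control and 5 only in Arid4bSCKO, so the spread between pools came only from the scaling of the libraries and not from the counts. Their FDR in the authors' deposited table was 4.38e-05 and 0.0033, and none passed the moderated test run without a filter on level. Of the other 37, 26 were higher and 11 lower, and 33 also passed the moderated test. Genes such as H2-M2 and Nkx1-2, singled out after their values were seen, were listed at 0 in control and are given no fold. The 10 largest rises and the 7 falls given above are those with a level in the upper part of the table, and 16 unnamed gene models among the 58 are only counted. Limiting the deposited p-values to the 19095 genes at a log2 level of 1 or more and readjusting them left 2 genes, Insc and Edf1, the latter singled out after its value was seen. The other 16 genes named by rule, Hrk and Wnt11 included, then missed the threshold, as they did with the minimum of 5 normalized counts fixed beforehand (readjusted p from 0.0563 to 0.0595).

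**Figure D1:**
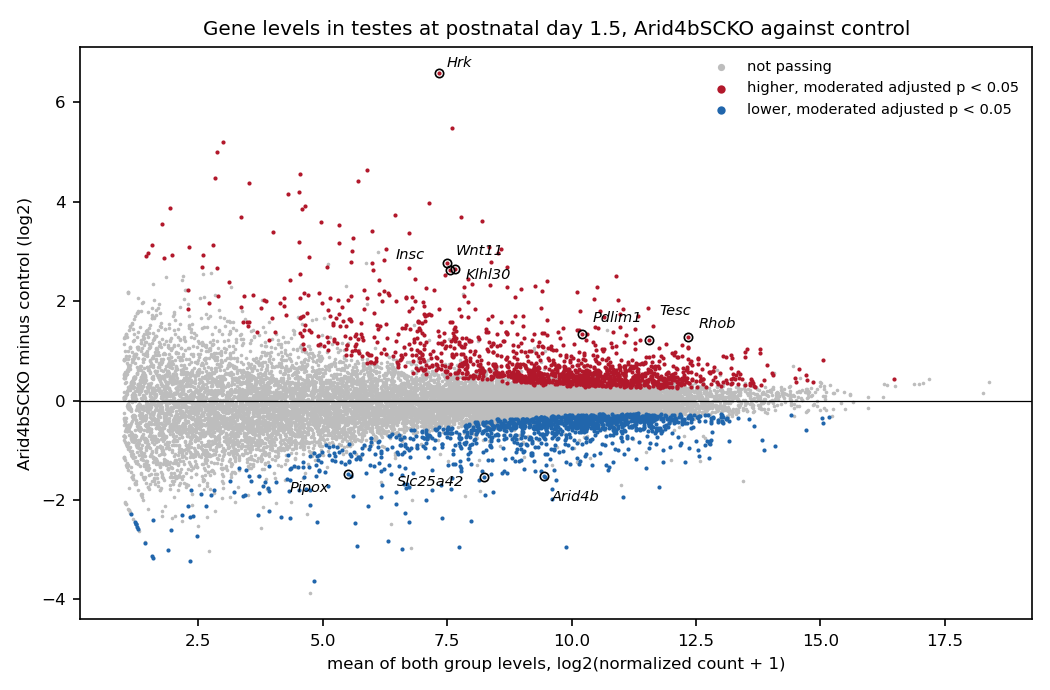
Difference between the groups (Arid4bSCKO minus control, log2) against the mean of both group levels (log2 of normalized count + 1) for 19095 genes, with 1 point per gene. Colored points passed the moderated test at an adjusted p below 0.05, circles mark named genes, and Hrk stands highest at 6.59 while Arid4b lies at -1.51.

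The moderated test, which shares information on the spread between genes of similar level, called 2641 of the 19095 genes, 1408 higher and 1233 lower. Of these, 1201 differed by at least 1.5-fold, 704 higher and 497 lower. The gene groups below were fixed before the data were examined. None of their 454 distinct members passed the authors' FDR, whereas 145 had an unadjusted p below 0.05 and 119 passed the moderated test. When the trend of the spread on level and robust fitting were dropped together from that test, 12 of the 119 kept their calls. They were 3 arrest, 3 immediate-early, 2 myoid, 2 Sin3 family (Arid4b and Sap30), 1 macrophage (C1qa) and 1 retinoic acid gene (Aldh1a1). No gene of the Sertoli cell, niche, germ cell or proliferation lists was called in that setting (0 in each). For the groups, "called" refers to the moderated test, and each list median is set against 10000 random lists of the same size and expression level. Random lists ignore that related genes vary together, so their percentiles describe these libraries. The cameraPR values below used a preset correlation of 0.01 unless stated. That correlation was assumed and not estimated, and a stronger one among related genes would give larger p-values. At 0.05 the cameraPR adjusted p was 0.00992 for the Sertoli cell list and 0.0014 for the proliferation list. It was 7.67e-09 for the macrophage list, 4.56e-05 for the arrest list and 7.54e-07 for the immediate-early list. Of the 23 lists with enough members, 7 had a median outside the central 95% of the random medians.

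Sertoli cell genes were lower as a group. Of 30 members, 12 were called lower and 3 higher, the median difference was -0.53, below every random list, and cameraPR gave an adjusted p of 1.09e-04. Nr5a1, which encodes the steroidogenic factor SF1, differed by -0.53 (95% interval -0.78 to -0.29) and Hsd17b1, a steroid dehydrogenase gene, by -1.94 (-3.21 to -0.67). These 2 had the smallest p-values of the list, and neither passed the authors' FDR. Further members were picked after their values were seen. Dhh, the hedgehog ligand of Sertoli cells, was at -0.86 (-1.60 to -0.13) and Dmrt1 at -0.72 (-1.30 to -0.13), both called. Amh, the anti-Müllerian hormone gene, was at -1.62, but its interval of -3.12 to -0.12 was wide and its moderated adjusted p was 0.111. Sox9, which directs Sertoli cell fate, was at 0.15 (-0.38 to 0.68) and Wt1 at -0.21 (-0.47 to 0.05), neither of them called. Cldn11, a tight junction gene, and Krt18 were called higher, at 0.95 (0.32 to 1.58) and 0.45 (0.12 to 0.78), but Krt18 was not called once the trend over transcript length was removed (0.32, adjusted p = 0.0902). With that trend removed, 14 members of the list were called lower and 1 higher. No member passed (0 of 30) when adjusted over the list alone, against 14 lower and 3 higher at an unadjusted p below 0.05.

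**Figure D2:**
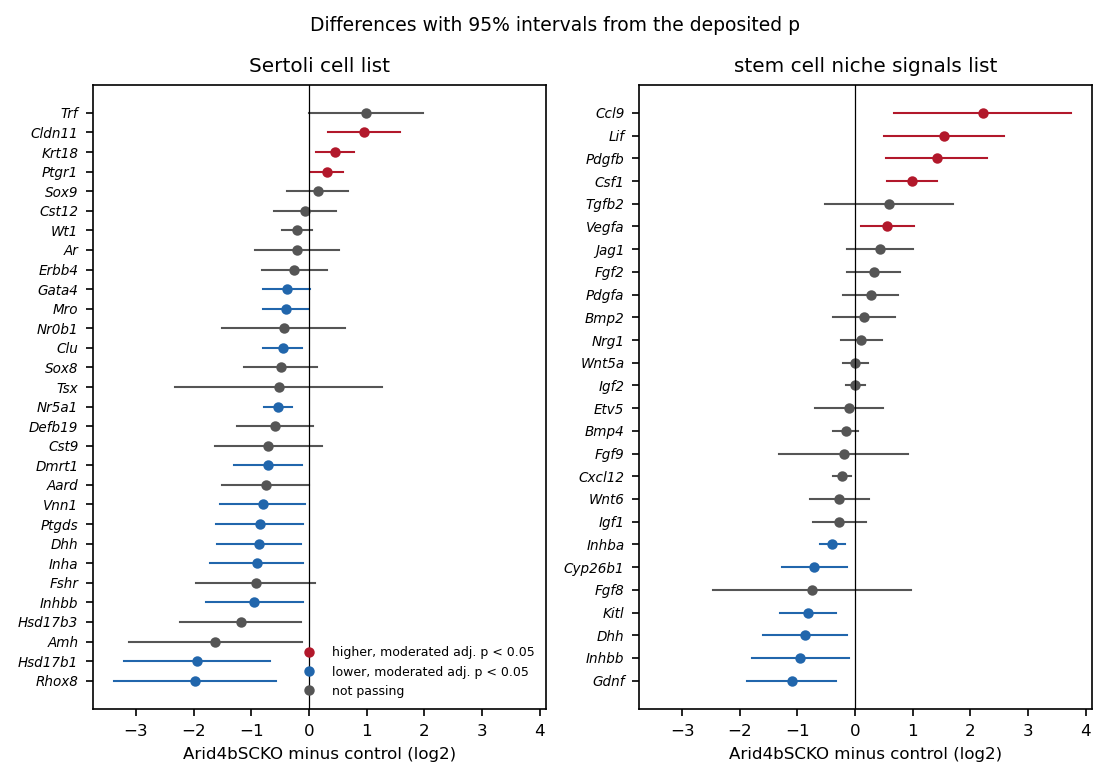
Difference (Arid4bSCKO minus control, log2) for each member of the Sertoli cell list (left) and of the stem cell niche list (right), with points at the difference of the group means and bars for the 95% interval implied by the deposited p. Of the Sertoli genes 12 were called lower and 3 higher, while the niche genes split into 6 lower and 5 higher.

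Signals of the stem cell niche moved in both directions. Of 26 genes, 6 were called lower and 5 higher, and the list median of -0.05 lay at percentile 29.8 of the random lists. Dhh and Inhbb, both called lower, also belong to the Sertoli cell list. The members with the smallest p-values were Csf1, the growth factor of macrophages, at 0.99 (95% interval 0.55 to 1.42), and Inhba, an activin subunit gene, at -0.40 (-0.61 to -0.18), which was not called once the length trend was removed (-0.28, adjusted p = 0.0642). Chosen after their values were seen, Gdnf, the ligand that sustains spermatogonial stem cells, was lower at -1.10 (-1.88 to -0.32), or 46.6% of control. Kitl, the ligand of the KIT receptor, was lower at -0.81 (-1.30 to -0.33), or 56.9% of control. Lif and Ccl9 were called higher, at 1.54 (0.50 to 2.58) and 2.21 (0.67 to 3.75). With p-values adjusted over the list alone 0 members passed, whereas 7 lower and 5 higher had an unadjusted p below 0.05.

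Germ cell genes had a median of -0.20, at percentile 0.18 of the random lists. Only Dppa4 (-0.86, 95% interval -1.66 to -0.05) and Dnmt3l (-1.29, -2.52 to -0.06) were called among 30 members, both lower, and cameraPR gave an adjusted p of 0.193. The count adjusted over the list alone was 0, and the same 2 genes had an unadjusted p below 0.05. Ddx4, a germ cell helicase gene given as an example of a level, was at -0.29 (-0.73 to 0.15). Gfra1, which encodes the receptor for GDNF, was at 0.04 (-0.65 to 0.73).

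Macrophage and leukocyte genes were higher in Arid4bSCKO. All 15 members had positive differences, 14 were called, and the median of 0.94 exceeded every random list (cameraPR adjusted p = 3.99e-13). C1qa, a complement component made by macrophages, was at 1.20 (95% interval 0.78 to 1.61) and Mrc1, the mannose receptor gene, at 0.52 (0.32 to 0.72). Pf4 was at 1.31 (0.51 to 2.10). The same number, 14, passed as higher when adjusted over the list alone. With the trend over transcript length removed 10 were called, and Cd14, Fcer1g, Lyz2 and Tyrobp were not (adjusted p = 0.0566, 0.237, 0.0558 and 0.0592), while Emr1 had no matched length. This higher level accompanied the lower Sertoli cell genes and the mixed niche signals above.

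Markers of the other cell types showed small or no shifts. Fetal Leydig cell genes had a median of -0.05, with 1 of 18 called higher (Tspo, 0.86, 95% interval 0.45 to 1.27) and 2 lower, and Thbs2 was at -0.15 (-0.23 to -0.07), or -0.04 with the length trend removed, and not called in either case. Peritubular myoid genes had a median of 0.09 over 14 members, with Tagln called higher (0.67, 0.51 to 0.83) and Synpo2 lower (-1.13, -1.54 to -0.72). Stromal genes had 2 of 20 called in each direction and a median of 0.01. Dpt was at 0.65 (0.32 to 0.99), and Cxcl12, the chemokine, at -0.23 (-0.38 to -0.08), or -0.13 with the length trend removed, and not called in either case. The hedgehog receptor gene Ptch1 was called lower at -0.89 (-1.49 to -0.28). Endothelial genes had a median of -0.20 at percentile 1.83, which moved to 10.3 once a trend over transcript length was removed. Robo4 was called higher (0.75, 0.22 to 1.28), 1 endothelial gene was called lower, and Ramp2 was at -0.29 (-0.45 to -0.12), called only with the length trend removed (-0.41, adjusted p = 0.0145). Of 9 erythroid and 13 mesonephric and epididymal genes none was called and none passed over the list alone. At an unadjusted p below 0.05 there were 0 erythroid genes and 2 mesonephric ones, Epcam at 0.35 (0.08 to 0.62) and Sfrp2 at 0.42 (0.02 to 0.83). Erythroid Hbb-y and Hbb-bs were at -0.49 (-1.17 to 0.19) and 0.69 (-0.73 to 2.12). Adjusted over the list alone, 1 myoid gene passed in each direction and 0 Leydig, stromal and endothelial genes did, where 5, 6 and 4 had an unadjusted p below 0.05.

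Proliferation genes were lower and arrest genes higher. Of 28 proliferation genes 11 were called lower and 0 higher, with a median of -0.30, below every random list (cameraPR adjusted p = 3.48e-06). The replicative helicase genes Mcm7 and Mcm2 were at -0.46 (95% interval -0.63 to -0.28) and -0.52 (-0.82 to -0.22). Of the proliferation genes 0 passed when adjusted over the list alone, with 9 lower at an unadjusted p below 0.05. Of 20 arrest and p53 target genes 7 were called higher and 0 lower, with a median of 0.28 at percentile 99.99 (cameraPR adjusted p = 5.24e-08). Gadd45b and Bbc3, the growth arrest gene and the gene of the apoptosis activator PUMA, were at 1.59 (1.15 to 2.03) and 1.90 (1.31 to 2.48). Cdkn1a, which encodes the inhibitor p21 and was chosen after its value was seen, was at 2.32 (1.15 to 3.49). When adjusted over the list alone 7 passed, all higher. With the length trend removed 5 were called, without Bax and Fas. Before that removal, 13 members of the arrest list were not called. These included the p53 targets Mdm2 (0.16), Ccng1 (0.22), Zmat3 (0.21) and Pmaip1 (-0.35).

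Immediate-early and stress genes were the other group with large differences. Of 21 members 13 were called higher and 1 lower, with a median of 0.70, above every random list (cameraPR adjusted p = 3.59e-11). Atf3, a stress-induced transcription factor gene, was at 3.70 (95% interval 2.68 to 4.71) and Ier2 at 0.51 (0.34 to 0.67). Junb was at 2.46 (1.41 to 3.50). The heat shock gene Hspa1b went the other way at -0.58 (-0.86 to -0.29). Counts adjusted over the list alone were 10 higher and 1 lower. Genes of this kind are known to respond to handling of tissue, and no record of dissection or RNA quality was used here. In the same comparison all 10 genes of the mitochondrial chromosome had positive differences, at 4.65% of the summed group means in Arid4bSCKO and 3.73% in control, and short transcripts were higher, with a rank correlation of -0.31 between difference and length.

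**Figure D3:**
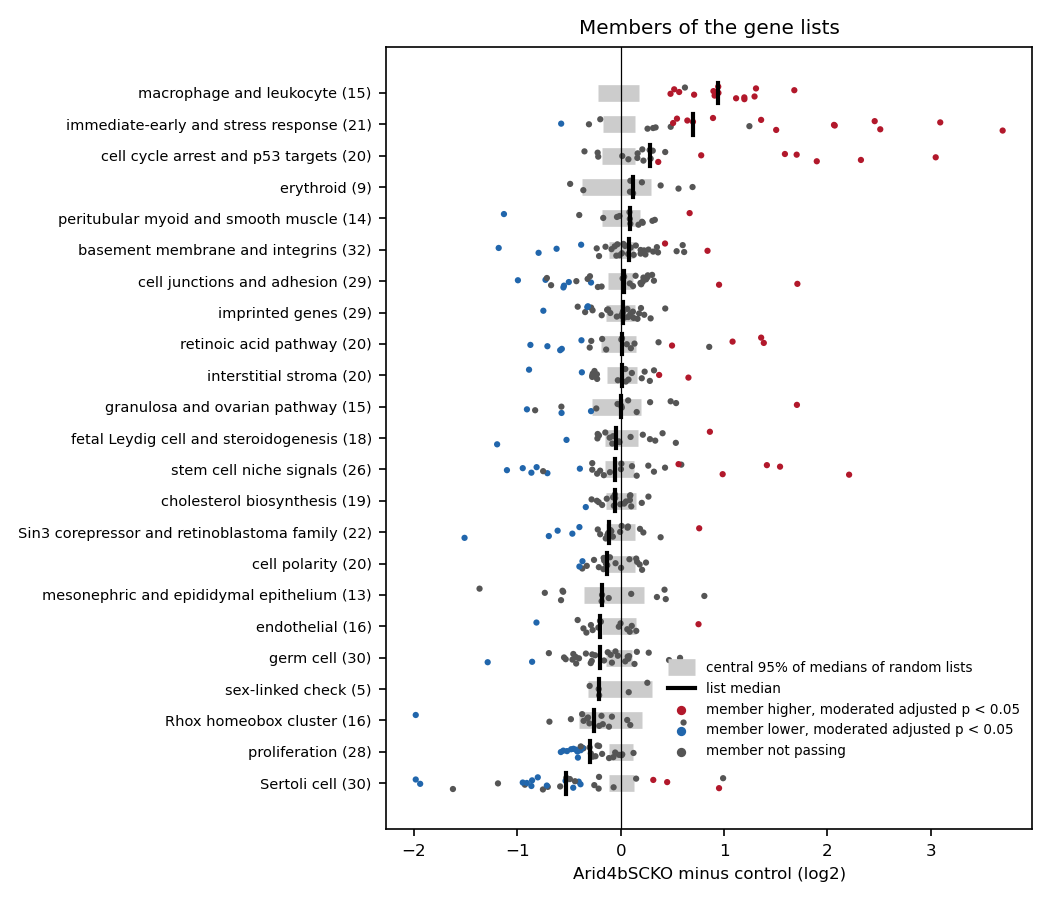
Difference (Arid4bSCKO minus control, log2) of the members of 23 gene lists, with 1 point per gene, a black bar at each list median and a gray bar for the central 95% of the medians of 10000 random lists of matched expression. The Sertoli cell and proliferation medians (-0.53 and -0.30) lie below the gray bar, and the macrophage, immediate-early and arrest medians (0.94, 0.70 and 0.28) lie above it. Those of the germ cell and endothelial lists (-0.20 each) also lie below their gray bars.

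Genes of attachment and cell shape were mixed. Of 32 basement membrane and integrin genes 2 were called higher and 4 lower, with Sparc, an extracellular matrix glycoprotein gene, called higher at 0.43 (95% interval 0.29 to 0.56) but not after centring on a trend over level (adjusted p = 0.069), and Dag1, the dystroglycan gene, at -0.80 (-1.15 to -0.44). The list median of 0.08 lay at percentile 88.5, and at 99.98 once the length trend was removed. The laminin chain gene Lama3 was called lower at -1.18 (-1.86 to -0.50) and the integrin gene Itga6 higher at 0.84 (0.46 to 1.22), both picked after their values were seen. Of 29 junction and adhesion genes 2 were called higher and 6 lower, with a median of 0.03. Jam2 was at -0.73 (-1.06 to -0.40) and Cadm1 at -0.55 (-0.85 to -0.26), and the gap junction gene Gja1, added after its value was seen, was at 50.2% of control (log2 interval -1.63 to -0.36). Of 20 polarity genes 2 were called lower and 0 higher. Pard6g was at -0.37 (-0.52 to -0.22), and Inadl, with the smallest p of the list, at -0.33 (-0.39 to -0.26) and not called. Adjusted over the list alone, 3 basement membrane genes passed as higher and 1 as lower, 2 polarity genes as lower and 0 junction genes, of which 10 had an unadjusted p below 0.05.

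Among partners of ARID4B, the Sin3 and retinoblastoma family list had 5 of 22 genes called lower and 1 higher, with a median of -0.11 at percentile 7.18. The called genes included Arid4b itself and Sap30, a Sin3 subunit gene, at 0.76 (95% interval 0.55 to 0.96). The list passed cameraPR at an adjusted p of 0.0136, but not at a preset correlation of 0.05 (adjusted p = 0.0961), and without Arid4b the unadjusted p was 0.0647. Rbl1, which encodes the pocket protein p107, was lower at -0.61 (-0.89 to -0.33). Of 29 imprinted genes 3 were called lower and 0 higher, with Ube3a at -0.32 (-0.46 to -0.19) and Peg10 at -0.75 (-1.08 to -0.42), and the median was 0.02. Once the length trend was removed, Ube3a was at -0.19 and not called (adjusted p = 0.153). Of 16 Rhox homeobox genes, Rhox8 alone was called, at -1.98 (-3.39 to -0.58). Rhox2d was at -0.69 (-1.86 to 0.48) and the Sertoli cell gene Rhox5 at -0.32 (-1.19 to 0.55). Adjusted over the list alone, 2 Sin3 family genes were higher and 7 lower, 2 imprinted genes were lower, and 0 Rhox genes passed, with 1 at an unadjusted p below 0.05.

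In the retinoic acid pathway 4 of 20 genes were called higher and 5 lower, with a median of 0.01. The dehydrogenase gene Aldh1a1 was at -0.59 (95% interval -0.73 to -0.44) and Rdh10, a retinol dehydrogenase gene, at 1.08 (0.59 to 1.58). Cyp26b1, the enzyme that degrades retinoic acid, was called lower at -0.71 (-1.28 to -0.14). Genes of the granulosa and ovarian pathway had a median of 0.00 over 15 members, with 1 called higher (Lgr5, 1.70, 0.82 to 2.59) and 3 lower. Amhr2, the receptor gene for anti-Müllerian hormone, was at -0.57 (-0.90 to -0.25), and Foxl2, an ovarian factor gene singled out after its value was seen, was at -0.24 (-2.59 to 2.11), near the floor. Of 19 cholesterol synthesis genes only Acat2 was called (-0.34, -0.53 to -0.15), and Mvd was at -0.14 (-0.21 to -0.06), or -0.22 with the length trend removed, and not called in either case. Adjusted over the list alone, 3 retinoic acid genes passed in each direction, 1 granulosa gene was higher and 4 lower, and 0 cholesterol genes passed, with 4 at an unadjusted p below 0.05.

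Differences also followed transcript length. Over 11412 genes at a log2 level of 7 or more, the rank correlation of the difference with length was -0.31 across genes, which are not independent replicates. The median difference fell stepwise from 0.17 in the shortest decile to -0.14 in the longest. Removing this trend left 2250 moderated calls, 1310 higher and 940 lower, of which 1932 were shared with the 2641. The Sertoli cell median was then -0.65, the proliferation median stayed at -0.30, and the macrophage and immediate-early medians were 0.82 and 0.70. Calls in smaller groups also shifted: basement membrane genes went to 4 higher and 3 lower, stromal genes to 1 in each direction, polarity genes to 1 lower, granulosa and imprinted genes to 2 lower, myoid and endothelial genes to 2 lower, and the Sin3 family to 2 higher. Niche genes went to 6 higher and 5 lower, and retinoic acid genes to 3 higher and 4 lower. Junction genes went to 5 lower and proliferation genes to 10 lower. The differences of the 10 mitochondrial chromosome genes ran from 0.28 to 1.41. None of the 10 passed either test, and 1 had an unadjusted p below 0.05. Of 5 sex-linked genes 0 were called and 0 passed when adjusted over the list alone. The Y-linked Uty, with the smallest p, was at -0.30 (95% interval -0.58 to -0.02), and Ddx3y was at -0.21 (-0.45 to 0.03). Xist, at mean log2 levels of 4.24 in Arid4bSCKO and 3.98 in control, differed by 0.26 (-3.52 to 4.03). So wide an interval implies that Xist varied strongly between pools, and its level in single pools was not analysed here.

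**Figure D4:**
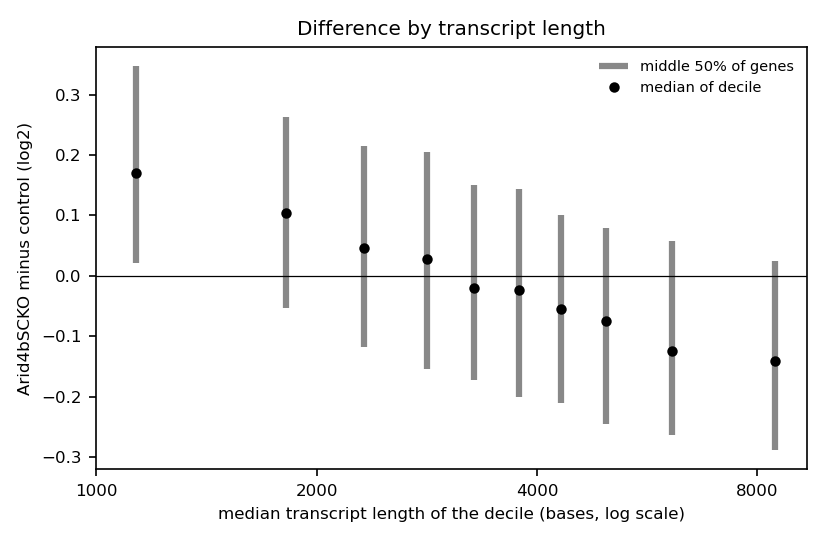
Difference (Arid4bSCKO minus control, log2) in deciles of transcript length for 11412 genes at a log2 level of 7 or more, with the median length of each decile on a log axis. Points are decile medians, which run from 0.17 to -0.14, and bars span the middle 50% of the genes.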

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

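No paired analysis was possible because the table holds only group means, and leaving out single pools, other scalings of counts, other pseudocounts, voom, fry and other splits of the 6 libraries could not be run for the same reason. All settings below other than the thresholds of 0.01 and 0.1, the 1.5-fold minimum and the minimum of 5 normalized counts were chosen after seeing the data. The count of 58 genes became 23 at an FDR of 0.01, 607 at 0.1 and 2 when the p-values were readjusted over genes with a mean of at least 5 normalized counts, as over genes at a level of 1 or more, since both filters remove the 21 genes with 1 read per library, whose small p-values ease the adjustment. It was 43 with a 1.5-fold minimum, 60 without the filled-in rows, and 2641 in the moderated test. The moderated count became 237 (164 higher, 73 lower) without the trend of the spread on level and robust fitting. It was 1201 with a 1.5-fold minimum, and stayed between 2250 and 2739 over the other filters, centrings and the length correction. The trend and robust fitting were dropped together, so the count of 237 cannot be credited to either, and its cause was not tested. The Arid4b level kept its direction and, unlike in the deposited test, passed in the moderated test (-1.51, adjusted p = 2.23e-05), after centring on the median (-1.50), after centring on a trend over level (-1.50), without the trend (-1.51, adjusted p = 0.0183) and less the length trend (-1.41). The number of lists outside the random range was 7, and it was 7 less the length trend and 6 for the ratio of medians. The lists were not all the same less the length trend. The endothelial list came inside the range (percentile 1.83, then 10.3) and the basement membrane list moved outside it (88.5, then 99.98). The lists that passed cameraPR, a different measure, numbered 6 at a correlation of 0.01, 5 at 0.05 and 6 less the length trend.

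Of 146 other genes followed through the settings, Zbtb16, with -0.05, was at 0.0377 less the length trend, and 2 more changed sign for the ratio of medians: Gfra1 (0.04, then -0.25) and Xist (0.26, then -0.50). None of the 3 was called. In the moderated test 82 of the 146 passed that had not passed the deposited FDR. Of the 99 called in the moderated test, 69 lost the call without the trend of the spread on level and robust fitting, and 30 kept it. Those lost include Dkc1, Nr5a1, Hsd17b1, Cldn11 and Gdnf, with adjusted p-values of 0.0828, 0.0688, 0.0744, 0.0782 and 0.0823. Less the length trend 13 lost the call, among them Suv420h1, Zfp740, Chsy1, Inhba, Krt18, Ube3a and Zim1. Centring on the median and on the trend over level cost 2 calls each, with Sparc among the latter, and dropping the filter cost 3. Depth limits genes at levels from 1 to 3, where the median SD of 0.81 leaves a 2-fold change within the error.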

Other observations

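The gene groups and tests of this part were chosen after the data were seen, except for 3 tests set before their results: those of expression level, of ribosomal and mitochondrial protein genes, and of transcript length in the Sertoli cell list. Genes of the integrated stress response, which acts through the transcription factor ATF4, were higher in Arid4bSCKO. Of 23 genes, 15 were called higher and 1 lower in the moderated test, and the median difference was 0.54. Chac1 was at 4.42 (95% interval 2.75 to 6.08), Trib3 at 2.79 (1.66 to 3.92) and Atf4 at 1.08 (0.53 to 1.63). In the moderated test without the trend on level and robust fitting, Atf4 lost its call (adjusted p = 0.0602), and Chac1 and Trib3 kept theirs. The amino acid synthesis gene Asns, another target of ATF4, was at 0.13 (-0.34 to 0.60) and not called. It was 1 of 7 members not called, with Phgdh at -0.12, Slc3a2 at 0.005 and Ddit4 at -0.24 among them. Slc7a5 was the member called lower, at -0.35. Counts adjusted over the list alone were 12 higher and 1 lower, and the list is not independent evidence of its direction, since it was written from these values.

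Chemokine, NF-kappaB and class I antigen genes were also higher. Of 24 genes 19 were called higher and 0 lower, with a median of 0.95. Cxcl10 was at 4.64 (95% interval 3.55 to 5.73), Cxcl1 at 3.40 (2.49 to 4.31), Ccl2 at 3.85 (1.35 to 6.34) and the class I gene H2-K1 at 1.33 (0.77 to 1.88). In the moderated test without the trend on level and robust fitting, Ccl2 lost its call (adjusted p = 0.0721). Cxcl10, Cxcl1 and H2-K1 kept theirs. B2m, the partner chain of class I molecules, was at 0.67 (0.55 to 0.79) and is the member of this list that passed the deposited FDR. Il6 was near the floor in both groups, with a difference of -0.49 (-3.00 to 2.02). These differences accompanied the higher macrophage genes (median 0.94).

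Ggps1, the gene next to Arid4b on chromosome 13, was lower by nearly the same amount, at -1.46 (95% interval -1.77 to -1.14), and ranked 4 among the falls in the moderated test, where Arid4b ranked 1. Its rank times 2 neighbours, over the genes tested, was 0.000419. Ggps1 was singled out after its value was seen, so this share does not test chance. The 2 genes overlap by 257 bases on opposite strands (Ggps1 14050659 to 14063488, Arid4b 14063232 to 14199603), and if counting ignored strand, that overlap, 4.38% of the Arid4b transcript length, would have to hold 57.3% of the normalized counts Arid4b lost, so shared reads cannot be ruled out but would need very uneven coverage. Within 5 Mb, 7 of 32 other genes were called (21.9%, exact 95% interval 9.28 to 40.0), against 14.8% elsewhere, which leaves a strain segment around the allele open. As a hypothesis, the recombined or null Arid4b allele may lower Ggps1 in cis. The 2 falls differed by 0.0564 (-0.26 to 0.38), and Tbce, the next gene, was at 0.19 (-0.07 to 0.45). Unlike the other intervals, that of the difference between the falls used moderated standard errors and a normal quantile. It treated the 2 genes as independent, although both were measured in the same pools. With both genes lower, the comparison cannot assign the differences of other genes to Arid4b alone.

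Shorter transcripts were higher in Arid4bSCKO, with a rank correlation of -0.31 across genes. Expression level does not account for it, since the median correlation within deciles of level was -0.32. Ribosomal and mitochondrial protein genes do not either, as the correlation without 265 of them was -0.30. A difference in RNA or library preparation between the groups cannot be told apart from genotype without values per library, because the decile medians, 0.31 apart from shortest to longest, fell at each of 9 steps, as either could produce.

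Sertoli cell genes were lower, with a median of -0.53. A lower share of Sertoli cells as the only cause argues for all of them falling alike, but the intervals of 26.7% of the 30 members excluded the list median, among them Cldn11 at 0.95 (0.32 to 1.58) and Sox9 at 0.15 (-0.38 to 0.68). Some of these genes are also expressed by other cells, which would blunt their fall, and a lower share alongside regulation stays open. The length trend argues in the other direction, since removing it moved the median to -0.65.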
